A study of Mus musculus with 6 samples.

How the data were processed

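Gene expression was measured by RNA sequencing in 6 libraries of mouse satellite cells, 3 cultured with 0.25% BAPN for 24 h and 3 without. Groups were taken from the labels' treatment entries and titles, and the replicate numbers from the titles. Per the labels' protocols, gastrocnemius muscle was digested, fibroblasts were reduced by repeated plating, and the remaining cells were grown on 4% matrigel, a basement membrane extract. The sources differ on 2 points: the mice were 8 weeks old in 1 label and 6 weeks in the growth protocol, and the differentiation medium held 4% horse serum in the series description and 10% fetal calf serum in the growth protocol. Per the labels' protocols, total RNA was extracted, libraries were made by an in-house method and sequenced in 1 lane as single reads of 60 nt. Most samples had an RNA integrity number above 8.1, and 2 samples, which the labels do not identify, were below 7.5. An effect of RNA quality on any group of genes therefore could not be separated out.

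Per the submitters' processing notes, cutadapt, STAR, HTSeq and DESeq2 were used with GRCm38 (mm10). Their versions, roles, annotation and strand setting are not given in the sources used here. Per the file headers, the authors deposited raw counts for 18864 gene symbols, with no pooling of libraries and 0 rows that name no gene. Beside them the authors deposited normalized counts, a signal that in every library is the count divided by 1 size factor. The authors also deposited their own comparison, with a log2 fold change, a signed linear fold change, a p-value and an adjusted p-value for each gene, and a mean of normalized counts. That mean is not the mean of the 6 libraries: it differs by over 10% for 8738 of the 13716 genes tested here. All deposited values are per gene symbol, so reads from paralogs and overlapping genes could not be separated.

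The analysis had been planned for normalized values. Because the table held raw counts, the test set beforehand for counts was used. Genes with a mean normalized count of at least 10 over the 6 libraries (13716) were tested in edgeR 4.0.16 (R 4.3.3) with glmQLFit and glmQLFTest, BAPN against control, without a block, scaled by the authors' size factors. These were 1.0677, 1.0737 and 0.9651 with BAPN and 0.9815, 0.9839 and 0.9047 in controls, against median-ratio factors from the 6 libraries alone of 1.0708, 1.0746 and 0.9577, and 1.0079, 1.0057 and 0.9204. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, and 503 genes had no count in any library. Log2 fold changes are edgeR estimates from counts, BAPN over control. With 3 libraries a group, p-values measure the spread between these libraries.

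Gene lists were fixed before the data were examined, as were the tests and most alternatives. There were 31 lists: myogenic regulators, satellite cell markers, sarcomere, excitation-contraction coupling, fusion, muscle energy metabolism, lysyl oxidases, collagens, elastic fibres and matricellular proteins, matrix proteases, TGF-beta, YAP and TEAD, SRF and actin, S phase, G2 and M phase, NRF2, unfolded protein response, p53, cholesterol synthesis, glycolysis and hypoxia, interferon, NF-kB, immediate early genes, mitochondrial transcripts, ribosomal proteins, and markers of fibroblasts, adipocytes, macrophages, endothelium, smooth muscle and Schwann cells or tenocytes. Each list was tested with limma 3.58.1 camera on the edgeR fit, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 31 lists. Counts of members that rose or fell use the adjustment over all genes and, beside it, the adjustment over the list alone. Some lists share members, so they are not independent.

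The genes named by rule were the 5 lysyl oxidase genes, a fixed panel of 12, the 8 genes with the largest and the 8 with the smallest log2 fold change among called genes with a group mean of at least 100 and no overlap between groups, and the 3 members of each list with the smallest p. They come to 117 genes, of which 105 were called. Positions are whole-gene spans, 1-based, in GRCm38 from GENCODE M21, which may not be the authors' annotation, and 18532 symbols matched it. By that annotation, 22 of the 117 share exonic sequence with another gene and are uncertain because no strand setting is given. For Islr and Tm7sf2 the other gene is on the same strand. For Adam8, Adamts4, Bhlhe40, Car9, Cdc20, Cebpa, Cxcl10, Eng, Fbn1, Fn1, Jam3, Lox, Loxl2, Loxl3, Mfap4, Notch3, Oasl1, Slc2a1, Tagln and Thbs1 it is on the opposite strand. Reads of Mt1, Cmpk2, the Rpl genes and other members of families with near copies or pseudogenes may also be shared.

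Pairing was checked from the data, since the titles share a replicate number between groups and the labels do not say what it marks. The deviations of same-numbered libraries from their group means correlated at 0.184, 0.191 and 0.366 for replicates 1, 2 and 3, across genes. BAPN replicate 1 correlated more strongly with control replicate 2 (0.229), and BAPN replicate 2 with control replicate 1 at 0.105. Deviations from a mean of 3 sum to 0, so a shift shared by the replicate 3 libraries alone would make all of these positive. The values therefore set replicate 3 apart but do not tell how replicates 1 and 2 pair. The replicate block and the pair medians rest on the numbers in the titles. Within groups, replicates 1 and 2 lay close together. The chi-square per gene between their counts was 2.13 with BAPN and 2.30 in controls, against 20.0 to 22.4 for pairs with replicate 3. The value of 1 is what sampling alone gives, so the libraries are not copies of the same counts, but library preparations of 1 culture would also exceed it. Whether replicates 1 and 2 come from the same isolation is not given in the sources used here. They were kept as separate libraries because the series description calls the replicates independent, and the counts were also computed with them summed. If they are not independent, the p-values are too small.

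Total counts per library were between 17125602 and 18682099. To test the fits on simulated data, counts were drawn for the 13716 genes of the comparison of BAPN with control, with 200 genes changed by a known amount. edgeR recovered 53.7% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 98.5% of those changed 4-fold, and called 12 of 13516 unchanged genes. Far fewer genes were changed than were called in the data, so these shares are not the recovery in the data. The libraries were drawn independently, so the false calls do not cover a dependence between replicates 1 and 2.

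The alternatives were TMM and upper quartile scaling, limma-trend with pseudocounts of 1, 0.5 and 10, no filter and a minimum mean of 50, a replicate block, library quality weights, each library left out in turn, DESeq2 1.42.0 with and without the block, the authors' deposited table, a 2-fold minimum, an adjusted p under 0.01, and for lists an estimated correlation, fry and ranks. With an estimated correlation, camera takes its degrees of freedom from the residuals of the 6 libraries, and with the preset from the number of genes. So few degrees of freedom raise p whatever the correlation. For p53 genes with the replicate block, the estimated correlation was -0.026, below the preset 0.01. Their camera adjusted p still went from 0.0083 to 0.43. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.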

Results

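RNA was sequenced from mouse satellite cells, the stem cells of skeletal muscle, that had been isolated from gastrocnemius muscle and moved to differentiation medium. For the last 24 h the cells were cultured with 0.25% BAPN (beta-aminopropionitrile), an irreversible inhibitor of the lysyl oxidases that cross-link collagen and elastin, or without it. Each condition had 3 replicates, which the series description calls independent. The total count per library was between 17125602 and 18617656 with BAPN (BAPN replicates 1 to 3) and between 18335559 and 18682099 without (control replicates 1 to 3). The labels present the comparison as a test of whether lysyl oxidase inhibition changes the differentiation of satellite cells.

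After 24 h with BAPN, cells had lower transcript levels of sarcomere proteins, of the calcium-release apparatus and of the myogenic regulators that drive differentiation, and higher levels of genes for glycolysis, hypoxia response, cholesterol synthesis and stress responses. Sarcomere genes had a median log2 fold change of -0.88, and glycolysis and hypoxia genes a median of 1.26, although with an estimated correlation none of the lists passed (camera adjusted p of 0.46 for sarcomere genes, 0.61 for excitation-contraction coupling, 0.41 for myogenic regulators and 0.11 for glycolysis). That form of the test has few degrees of freedom with 6 libraries, so it does not tell how far correlation between genes accounts for the calls. Of 13716 genes tested, 2140 were higher and 2850 lower with BAPN at an edgeR adjusted p under 0.05, of which 545 and 405 changed at least 2-fold. The excess of lower genes depends on the scaling by the authors' size factors, since TMM scaling gave 2450 higher and 2381 lower and upper quartile scaling 2433 and 2430. The BAPN and control libraries did not overlap for 6986 genes (50.9%), against 10% by chance for 6 independent libraries, which the closeness of replicates 1 and 2 leaves in doubt. The first principal component, with 67.1% of the variance, parted the groups. The second, with 16.5%, parted replicate 3 from replicates 1 and 2 in both groups. Without BAPN replicate 2, the count of lower genes was 1862. When replicates 1 and 2 of each group, which lay close together, were summed into 1 library, 716 genes were higher and 809 lower, and without both libraries of replicate 3, 3223 and 4265. The last 2 counts rest on replicates 1 and 2 alone and are too high if these are not independent.

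**Figure D1:**
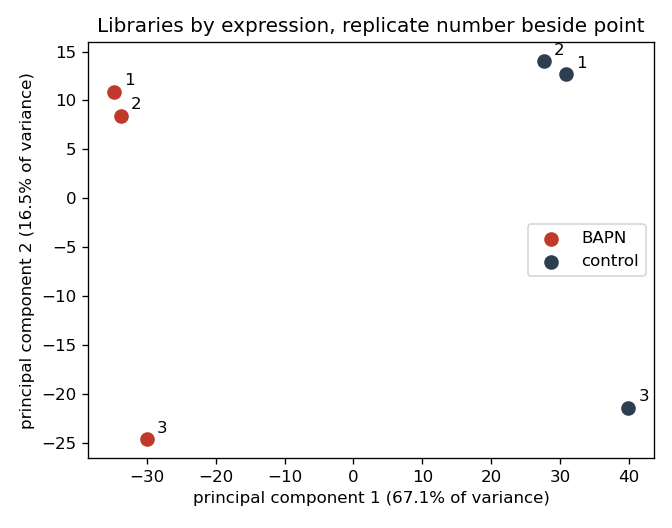
Scores of the 6 libraries on principal components 1 and 2 of log2 normalized counts, with the percent of variance on each axis and the replicate number beside each point. BAPN libraries (red) lie at the left of component 1, which holds 67.1% of the variance, and replicate 3 of both groups lies at the bottom of component 2.

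The 5 lysyl oxidase genes, whose products BAPN inhibits, changed in both directions. Lox (chromosome 18, 52516067 to 52529867 in GRCm38) had a normalized count of 679 ± 103 with BAPN and 400.3 ± 86.8 in controls (SD, n = 3 each), a log2 fold change of 0.76 (SE 0.17, edgeR adjusted p = 0.0099). Loxl2 (chromosome 14, 69609068 to 69695834) also rose, by 0.95 on the log2 scale (SE 0.12, edgeR adjusted p = 0.0011), from the lowest level but 1 in the family, 202 ± 11.9 with BAPN and 104 ± 9.25 in controls. Loxl1 (chromosome 9, 58287738 to 58313186), Loxl3 (chromosome 6, 83034173 to 83052562) and Loxl4 (chromosome 19, 42593982 to 42612813) fell, with log2 fold changes of -0.58, -0.68 and -0.69 (edgeR adjusted p = 0.011, 0.0097 and 0.027). Loxl1 was the most abundant member in controls, at 983 ± 57.0 with BAPN and 1466 ± 279.6 in controls, and Loxl4 the least, at 44.5 ± 8.60 with BAPN and 71.9 ± 8.47 in controls. As a list, 2 rose and 3 fell (2 and 3 adjusted over the list alone), the median was -0.58, the mean -0.05 and the direction of the test against other genes upward, so that these differ in sign (camera adjusted p = 0.94). Loxl4 lost its call without BAPN replicate 2 (edgeR adjusted p = 0.093), control replicate 2 (0.085) or control replicate 3 (0.060). With replicates 1 and 2 summed, Lox (0.054), Loxl3 (0.076) and Loxl4 (0.085) were not called.

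**Figure D2:**
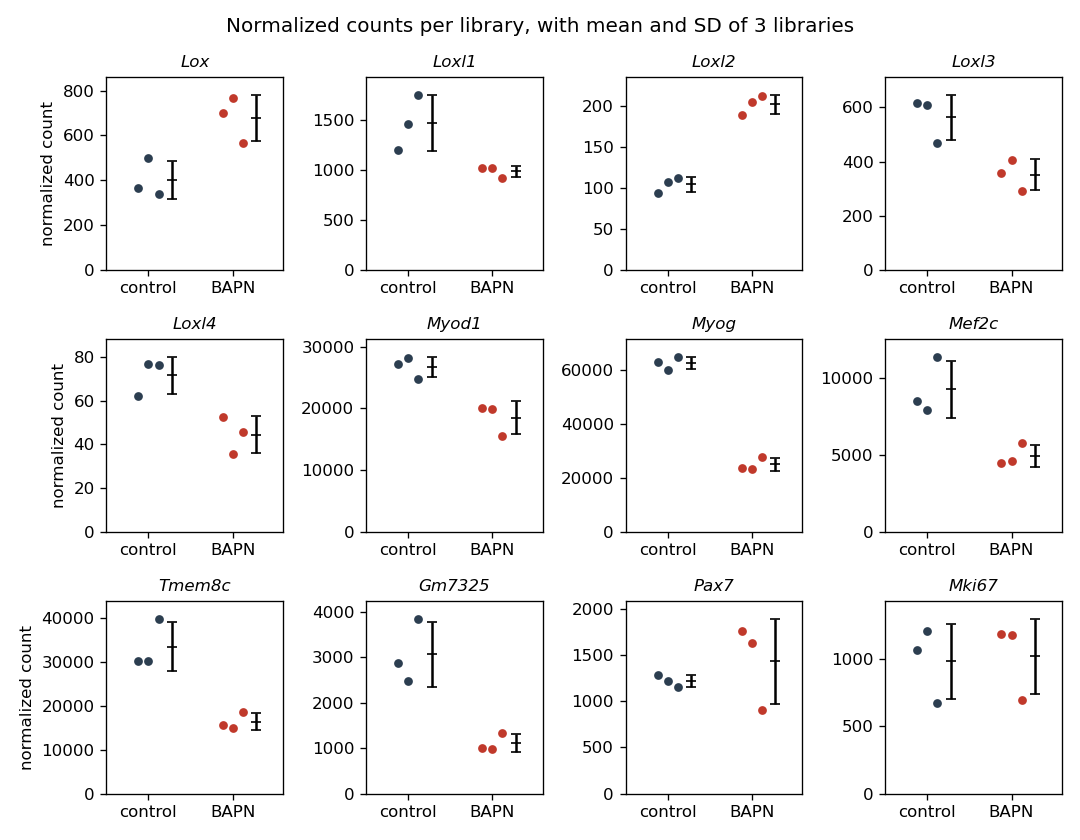
Normalized counts (linear axes from 0) of 12 genes in each library, control in dark blue and BAPN in red, replicates 1 to 3 from left to right, with the mean and SD of 3 libraries beside them. The 3 BAPN libraries lie below the 3 controls for Myog, Myod1, Mef2c, Tmem8c and Gm7325 and above them for Lox and Loxl2, while the groups overlap for Pax7 and Mki67.

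Among the myogenic regulators, myogenin fell most clearly. Myog (chromosome 1, 134289989 to 134292548), which encodes the transcription factor of terminal differentiation, had a normalized count of 24989 ± 2509 with BAPN and 62630.0 ± 2361 in controls, a log2 fold change of -1.33 (SE 0.09, edgeR adjusted p = 1.4e-04). Myod1 (chromosome 7, 46376474 to 46379099), a myogenic determination factor, and Mef2c (chromosome 13, 83504034 to 83667080), a partner of these factors, fell by smaller amounts, with log2 fold changes of -0.53 and -0.90 (edgeR adjusted p = 0.0085 and 0.0036). Of 19 regulators and early differentiation genes, 2 rose and 12 fell (2 and 14 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 1.2e-04; adjusted p = 0.41 with an estimated correlation). Ankrd2, a stretch-responsive muscle protein, had a log2 fold change of -2.42 (edgeR adjusted p = 2.1e-04). The members that rose were Eya1, a partner of homeobox factors (0.95), and Igfbp5, an insulin-like growth factor binding protein (1.39). Vgll3, a cofactor of TEAD factors, fell by 0.48 on the log2 scale (edgeR adjusted p = 0.0032). With replicates 1 and 2 summed, Myod1 (edgeR adjusted p = 0.077) and Vgll3 (0.059) were not called.

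The contractile machinery was lower as a group. Of 56 sarcomere genes, 0 rose and 46 fell (0 and 48 adjusted over the list alone), with log2 fold changes from -1.97 to -0.27 and medians of -0.92, -0.82 and -0.96 in replicate pairs 1, 2 and 3 (camera adjusted p = 3.6e-17; adjusted p = 0.46 with an estimated correlation). Myom3, an M-band protein, had a normalized count of 4492 ± 253 with BAPN and 10576 ± 1029.5 in controls, Tnnt1, slow troponin T, 6645 ± 451 with BAPN and 13108 ± 1171 in controls, and Obsl1, a cytoskeletal linker of the M-band, 6532 ± 411 with BAPN and 11398 ± 697 in controls, with log2 fold changes of -1.24, -0.98 and -0.80 (edgeR adjusted p = 1.4e-04, 3.0e-04 and 3.7e-04). Of 33 genes of excitation-contraction coupling and the neuromuscular synapse, 1 rose and 20 fell (1 and 23 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 2.8e-05; adjusted p = 0.61 with an estimated correlation). With the replicate block, 2 of them rose and 25 fell, and without BAPN replicate 1 or BAPN replicate 2, 11 fell in each case. Jph2, which holds the junctional membranes together, Stac3 and the calcium channel subunit Cacng1 fell (-0.75, -0.82 and -0.99), and the member that rose was Ache, acetylcholinesterase (0.68, edgeR adjusted p = 0.029), which was not called without BAPN replicate 2, BAPN replicate 3, control replicate 1 or control replicate 2. Genes of muscle energy metabolism went both ways. Of 23, 5 rose and 7 fell (5 and 7 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.94). Those that rose were Hk2 (1.79), Ppp1r3c (1.35), Ppargc1a (0.72), Ldha (0.71) and Pdk4 (0.51), of which Hk2 and Ldha also stand in the glycolysis list. The number that fell was 4 without BAPN replicate 1 or BAPN replicate 2. The median was -0.33 without BAPN replicate 3, -0.24 and -0.23 without control replicates 1 and 2, and 0.020 without control replicate 3.

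Both genes of the muscle fusion pair fell. Myomaker, listed under its older symbol Tmem8c (chromosome 2, 27061636 to 27072179), had a normalized count of 16423 ± 1997 with BAPN and 33447 ± 5583 in controls (log2 fold change -1.03, SE 0.13, edgeR adjusted p = 0.0013). Myomixer, listed as Gm7325 (chromosome 17, 45600971 to 45602102), had 1107 ± 193 with BAPN and 3059 ± 707 in controls (log2 fold change -1.47, SE 0.18, edgeR adjusted p = 1.0e-03). Of all 29 fusion and adhesion genes, 4 rose and 9 fell (5 and 11 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.14, 0.016 with the replicate block, and 0.58 with the block and an estimated correlation). Without BAPN replicate 2 the median was -0.21. The list passed without both libraries of replicate 3 (camera adjusted p = 0.021), where only the close replicates 1 and 2 remain, and with fry (fry adjusted p = 0.015). It did not pass with replicates 1 and 2 summed (camera adjusted p = 0.097, with 1 higher and 4 lower). The adhesion molecules Cdh15, M-cadherin, and Jam3 fell (-0.54 and -0.88), and Stab2, Arhgap26, Dock5 and Anxa5 rose (1.03, 0.98, 0.82 and 0.53). Members of a list that are named because few of them moved one way were chosen after their values were seen, here and below, except where they were among the genes fixed by rule.

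Markers of satellite cells and progenitors did not pass as a list in the main fit and were lower in part of the settings. Pax7 (chromosome 4, 139737062 to 139833528), the transcription factor that marks satellite cells, had a normalized count of 1429 ± 462 with BAPN and 1220.5 ± 65.9 in controls (log2 fold change 0.23, SE 0.22, edgeR adjusted p = 0.44), and Myf5, a factor of activated progenitors, 424 ± 186 with BAPN and 413 ± 21.3 in controls (0.04, edgeR adjusted p = 0.93). Both depended on BAPN replicate 3. Without it Pax7 was called higher (0.47, edgeR adjusted p = 0.0021) and Myf5 lower (-0.38, edgeR adjusted p = 0.012). Of 24 progenitor markers, 3 rose and 9 fell (3 and 9 adjusted over the list alone), or 5 and 13 with the replicate block, with a median of -0.25 (camera adjusted p = 0.090). Without BAPN replicate 3 the median was -0.15. That list passed without a filter (camera adjusted p = 0.031), with replicates 1 and 2 summed (0.043), without BAPN replicate 1 (0.024), BAPN replicate 2 (0.044) or control replicate 3 (0.0066), and without BAPN replicate 3, 6 members rose. With an estimated correlation its camera adjusted p was 0.62, and 0.80 with the replicate block as well. The Notch targets Heyl and Hey1 and the receptor Notch3 fell (-4.48, -1.26 and -0.97), and Cxcr4, Cd34 and Id2 rose (1.30, 1.22 and 1.00).

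Genes of the G2 and M phases did not shift as a group, and S phase genes were higher in part of the settings. Mki67, a marker of cycling cells, had a normalized count of 1021 ± 281 with BAPN and 986 ± 279 in controls (edgeR adjusted p = 0.89), and replicate 3 had the lowest value in both groups. Of 30 genes of the G2 and M phases, 0 rose and 0 fell (0 and 0 adjusted over the list alone) by edgeR, but 3 rose and 7 fell with the replicate block, and 4 fell without control replicate 3. Their median was -0.03, or between -0.22 (without control replicate 3) and 0.13 (without BAPN replicate 3) with 1 library left out, and the test against other genes pointed upward (camera adjusted p = 0.94). At an unadjusted p under 0.05, 0 of them passed in edgeR, and 0 passed the adjusted threshold in DESeq2. The 3 with the smallest p, Anln, Cdc20 and Ccnb2, had log2 fold changes of 0.40, -0.38 and -0.28 (edgeR adjusted p = 0.18, 0.18 and 0.20, and 9.8e-04, 0.0028 and 0.015 with the replicate block). Cdc20 and Ccnb2 were called without control replicate 3 (edgeR adjusted p = 0.019 and 0.047). Of 30 S phase genes, 5 rose and 1 fell (2 and 1 adjusted over the list alone), or 14 and 5 with the replicate block, with a median of 0.22 (camera adjusted p = 0.24, 0.032 with the block, and 0.655 with the block and an estimated correlation). That list passed without BAPN replicate 3 (camera adjusted p = 0.041, with 9 higher) or control replicate 2 (0.042, with 4 higher). The pair medians of S phase genes were 0.23, 0.18 and 0.25. Without BAPN replicate 1 or BAPN replicate 2, 1 of them was higher (camera adjusted p = 0.61 and 0.48), and without control replicate 1 or control replicate 3, 3 were (0.069 and 0.84). The median was 0.37 without BAPN replicate 3, 0.15 without BAPN replicate 2 and 0.065 without control replicate 3. With replicates 1 and 2 summed, 1 gene was higher and the list did not pass (camera adjusted p = 0.16). The replication licensing factor Cdt1 (1.16), E2f1 (0.78), Pcna (0.65), Slbp (0.43) and Mcm7 (0.40) rose, and Ccne1, cyclin E1, fell (-1.31). Pcna lost its call without BAPN replicate 1 (edgeR adjusted p = 0.057), without BAPN replicate 2 (0.061) and with replicates 1 and 2 summed (0.10).

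Genes for glycolysis and the response to low oxygen rose almost without exception. Of 29, 28 rose and 0 fell (28 and 0 adjusted over the list alone), with a median of 1.26 and pair medians of 1.44, 1.33 and 1.03 (camera adjusted p = 9.2e-58; adjusted p = 0.11 with an estimated correlation). The member that did not pass was Aldoa, an aldolase (0.21, edgeR adjusted p = 0.18). Slc2a1, the glucose transporter GLUT1 (chromosome 4, 119108711 to 119137983), had a normalized count of 9142 ± 113 with BAPN and 1868 ± 113 in controls (log2 fold change 2.29, SE 0.07, edgeR adjusted p = 9.2e-06). Egln1 and Egln3, the prolyl hydroxylases that mark hypoxia-inducible factor for degradation, rose by 1.80 and 1.78 on the log2 scale (edgeR adjusted p = 2.4e-05 for each). Cholesterol synthesis genes also rose, 23 of 25 (23 adjusted over the list alone), with a median of 0.90 (camera adjusted p = 9.5e-18; adjusted p = 0.41 with an estimated correlation). Their median was smaller in replicate pair 3 (0.32) than in pairs 1 and 2 (1.29 and 1.26). Tm7sf2 and Acat2 had log2 fold changes of 1.68 and 1.62 (edgeR adjusted p = 9.9e-05 and 4.8e-04).

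Stress response genes were higher as well. Of 35 genes of the unfolded protein and integrated stress response, 20 rose and 1 fell (23 and 1 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 6.8e-10; adjusted p = 0.46 with an estimated correlation). Their pair medians were 0.53, 0.58 and 1.05, so that here pair 3 was the highest. Trib3, a pseudokinase induced by ATF4 and CHOP, had a normalized count of 2330.2 ± 1356 with BAPN and 143 ± 54.2 in controls, the BAPN libraries differing widely. Vldlr (3.06) and Ddit4, an inhibitor of mTORC1 (0.93), rose, and Calr, calreticulin, fell (-0.29, edgeR adjusted p = 0.023). Calr was not called without BAPN replicate 1, BAPN replicate 2, control replicate 1 or control replicate 2, and 3 members fell without BAPN replicate 3. Of 27 oxidative stress and NRF2 genes, 18 rose and 1 fell (19 and 2 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 9.5e-09; adjusted p = 0.31 with an estimated correlation). Mt1, a metallothionein, and Pgd, of the pentose phosphate pathway, rose (1.23 and 0.80), and Akr1b8 fell (-0.67). Of 29 p53 response and apoptosis genes, 12 rose and 4 fell (12 and 4 adjusted over the list alone), with a median of 0.11, or 0.065 without control replicate 3 (camera adjusted p = 0.0088; adjusted p = 0.41 with an estimated correlation). That list lost its call in limma-trend (camera adjusted p = 0.054 to 0.059) and with ranks (0.052), and without BAPN replicate 1 or BAPN replicate 2, 2 members fell. Gdf15, a stress-induced cytokine, and Bcl2l11, a pro-apoptotic protein, rose (1.85 and 1.08). Those that fell were Pmaip1 (-0.75), Cdkn1a (-0.58), Eda2r (-0.40) and Aen (-0.21), of which Cdkn1a, a cell cycle inhibitor, is also a member of the myogenic list.

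Immediate early, interferon and NF-kB genes were higher. Of 29 immediate early genes, 16 rose and 3 fell (18 and 3 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 2.5e-09; adjusted p = 0.19 with an estimated correlation). Ier3, Dusp4 and Spry2, feedback genes of growth factor signalling, rose by 2.03, 1.38 and 1.11 on the log2 scale (edgeR adjusted p = 9.6e-05, 2.4e-04 and 1.8e-04), and Dusp2, Zfp36 and Nr4a1 fell (-0.57, -0.49 and -0.29). Of 28 interferon response genes, 13 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 3.9e-05; adjusted p = 0.31 with an estimated correlation). Rsad2, Oasl1 and Cmpk2 had log2 fold changes of 2.67, 3.18 and 2.05. Control levels were low for Oasl1, at 99.2 ± 42.6 with BAPN and 10.9 ± 2.14 in controls. The same held for Cmpk2, at 85.8 ± 14.9 with BAPN and 20.8 ± 7.03 in controls. Of 21 NF-kB and cytokine genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 0.0048; adjusted p = 0.46 with an estimated correlation). Il33, Ccl5 and Tnfaip3 rose (1.48, 2.86 and 0.39), Ccl5 from a control level of only 2.77 ± 2.11, and Vcam1, an adhesion molecule, fell (-0.71). Without BAPN replicate 1, 4 of these genes rose, and without control replicate 1, 5, while without control replicate 3, 2 fell. With replicates 1 and 2 summed, Tnfaip3 was not called (edgeR adjusted p = 0.069).

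Collagen genes were lower as a list, matrix proteases were lower in part of the settings, and genes of elastic fibres and matricellular proteins did not shift together. Col1a1 (chromosome 11, 94936224 to 94953042), a chain of collagen I, had a normalized count of 1431 ± 225 with BAPN and 2302 ± 509.7 in controls (log2 fold change -0.69, SE 0.17, edgeR adjusted p = 0.017). It lost its call without BAPN replicate 1 (edgeR adjusted p = 0.060) or control replicate 2 (0.051). Of 31 collagen and collagen-processing genes, 3 rose and 16 fell (4 and 19 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 8.2e-04; adjusted p = 0.41 with an estimated correlation). Those that rose were the prolyl and lysyl hydroxylases P4ha2 (1.99), Plod2 (0.85) and P4ha1 (0.47), enzymes rather than chains, and P4ha1 also stands in the hypoxia list. Col3a1 is also among the fibroblast markers, whose median was -0.37. Adamts2, a procollagen protease, fell (-1.13, edgeR adjusted p = 2.3e-04). Of 21 matrix proteases and inhibitors, 2 rose and 10 fell (2 and 12 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.026; adjusted p = 0.46 with an estimated correlation). That list lost its call with library quality weights (camera adjusted p = 0.056) and in limma-trend (0.070 to 0.075), and 1 member rose without BAPN replicate 1, BAPN replicate 2, control replicate 1 or control replicate 2. Adam8, Adamts4 and the inhibitor Timp2 fell (-1.19, -0.94 and -0.71), and Mmp19 and Ctsk rose (1.47 and 0.70). Of 34 genes of elastic fibres, fibronectin and matricellular proteins, 4 rose and 8 fell (4 and 8 adjusted over the list alone), or 7 and 12 with the replicate block, with a median of -0.36 (camera adjusted p = 0.41). That median was -0.17 without BAPN replicate 3 and -0.13 without control replicate 3. Fbn1, fibrillin 1, and Thbs1, thrombospondin 1, fell (edgeR adjusted p = 6.2e-04 and 0.0019), while Spp1, osteopontin, Fbln5, Thbs2 and Tnc rose (1.21, 1.12, 0.59 and 0.38). Fn1, fibronectin, had a normalized count of 8316 ± 157 with BAPN and 7530.0 ± 275 in controls and a log2 fold change of 0.14 (edgeR adjusted p = 0.092), and passed with TMM scaling (edgeR adjusted p = 0.041), upper quartile scaling (0.041) and DESeq2 (DESeq2 adjusted p = 0.037).

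The list of SRF, MRTF and actin cytoskeleton genes was lower. Of 35, 1 rose and 18 fell (3 and 22 adjusted over the list alone), or 4 and 24 with the replicate block, with a median of -0.32 (camera adjusted p = 2.2e-05; adjusted p = 0.20 with an estimated correlation). Myl9, Tagln and Fhl1 had log2 fold changes of -1.44, -1.33 and -1.21 (edgeR adjusted p = 9.7e-05, 4.0e-04 and 1.8e-04). Tagln, Acta2 and Lmod1 are also smooth muscle and pericyte markers, whose median was -0.76, and the gene that rose was Mkl2, an SRF coactivator (0.34), while 3 rose without BAPN replicate 3. Cfl2, the muscle isoform of the actin-severing protein cofilin, fell by 0.46 on the log2 scale (edgeR adjusted p = 0.029). Its call was lost without BAPN replicate 1 (edgeR adjusted p = 0.097), BAPN replicate 2 (0.10), control replicate 1 (0.069) or control replicate 3 (0.072), and with replicates 1 and 2 summed (0.15). Genes of YAP, TEAD and Vestigial-like factors did not shift together. Of 25, 5 rose and 9 fell (6 and 9 adjusted over the list alone), with a median of -0.19 (-0.093 without BAPN replicate 3) and a mean of 0.03 (camera adjusted p = 0.70). Wwtr1, which encodes the coactivator TAZ, Wwc1, Nt5e, F3 and Lats1 rose (0.63, 0.62, 1.71, 1.40 and 0.25), and Ajuba fell (-0.48, edgeR adjusted p = 0.0025, and 0.054 with replicates 1 and 2 summed). The number of these genes that fell was 5 without BAPN replicate 2 and 4 without control replicate 1 or 2, and 3 rose without BAPN replicate 1. With replicates 1 and 2 summed, 3 rose and 0 fell by edgeR (5 and 5 at an unadjusted p under 0.05). Of 31 TGF-beta and BMP response genes, 7 rose and 6 fell (9 and 7 adjusted over the list alone), or 9 and 12 with the replicate block. Their median was -0.07, or between -0.20 (without BAPN replicate 1) and 0.026 (without control replicate 2) with 1 library left out, and the test against other genes pointed upward (camera adjusted p = 0.82). Without BAPN replicate 1, BAPN replicate 2 or control replicate 1, 4 of them rose in each case. Snai2 and Bhlhe40 rose (1.42 and 1.95), and Pmepa1 fell (edgeR adjusted p = 0.0017).

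**Figure D3:**
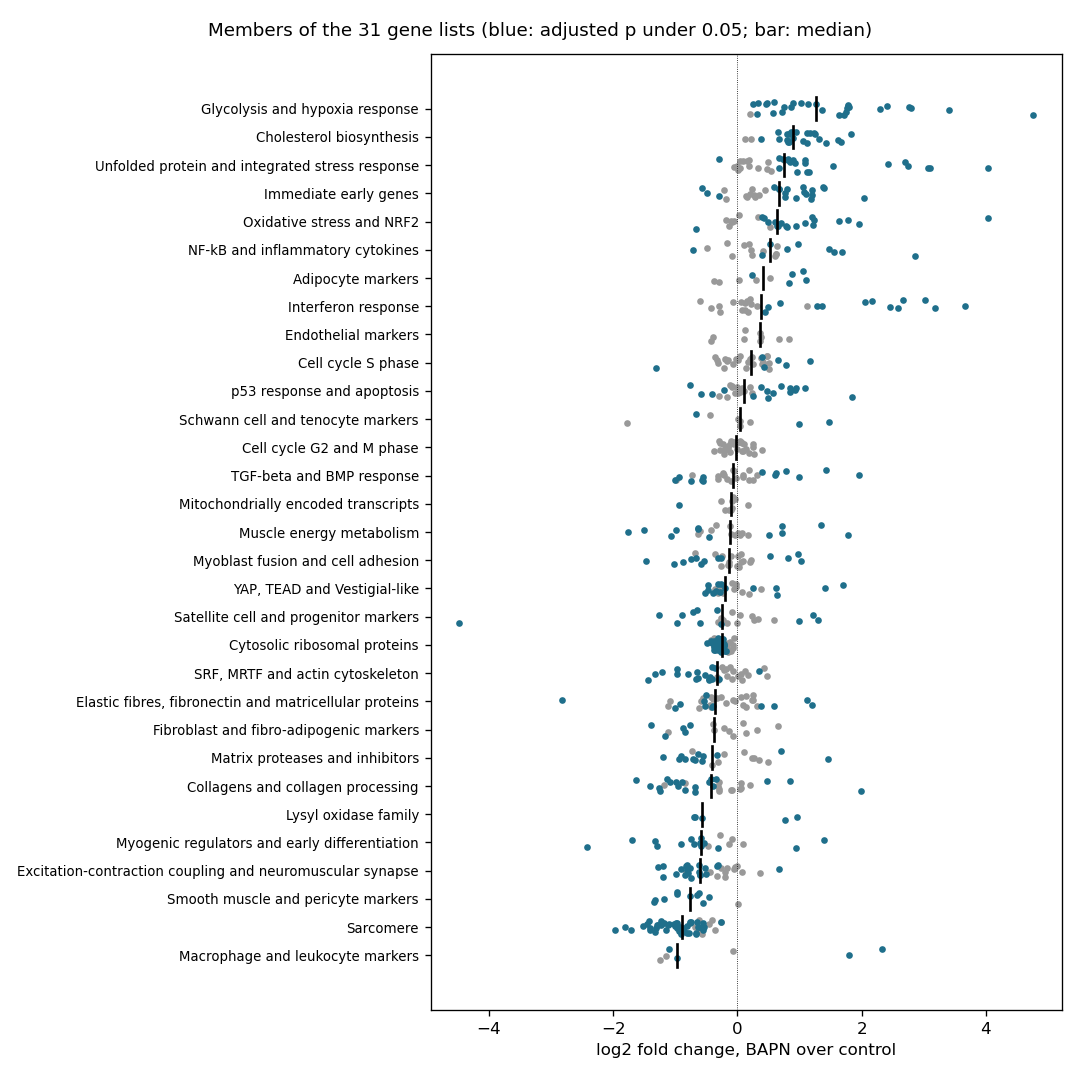
Log2 fold change (BAPN over control) of each tested member of the 31 gene lists, ordered by list median (black bars). Blue points passed an edgeR adjusted p of 0.05 and grey points did not. Glycolysis and hypoxia genes lie highest, with a median of 1.26, and the sarcomere list, with a median of -0.88, lies below nearly all others.

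Markers of other cell types, cytosolic ribosomal protein genes and mitochondrial transcripts moved with the groups in part. Smooth muscle and pericyte markers were lower with BAPN: of 11, 0 rose and 10 fell (0 and 10 adjusted over the list alone), with a median of -0.76 (camera adjusted p = 8.5e-07; adjusted p = 0.19 with an estimated correlation). Cspg4 and Acta2 had log2 fold changes of -1.34 and -0.97, and the member that did not pass was Pdgfrb (0.01). Of 15 fibroblast and fibro-adipogenic markers, 0 rose and 5 fell (0 and 5 adjusted over the list alone), or 1 and 8 with the replicate block, with a median of -0.37 (camera adjusted p = 0.025, 0.088 without BAPN replicate 3; adjusted p = 0.46 with an estimated correlation). That median was -0.25 without BAPN replicate 1 and -0.22 without control replicate 3. The list also lost its call with library quality weights (camera adjusted p = 0.20), in limma-trend (0.074 to 0.086), without a filter (0.088), with a minimum mean of 50 (0.074) and with ranks (0.058), so that its fall depends on the processing. Those that fell were Gpx3 (-1.39), Cd248 (-1.16), Ly6a (-0.88), Col3a1 (-0.84) and Lsp1 (-0.76). Of 10 adipocyte markers, 5 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.035, 0.066 without control replicate 1 and 0.058 without control replicate 2; adjusted p = 0.46 with an estimated correlation). That median was 0.26 without BAPN replicate 1 or control replicate 1. The markers that rose were Scd1 (1.11), Cebpa (1.06), Lipe (0.88), Fasn (0.83) and Pnpla2 (0.23), lipid metabolism genes that cells other than adipocytes also express. With replicates 1 and 2 summed the list lost its call (camera adjusted p = 0.071), as it did without a filter (0.075), and Scd1 (edgeR adjusted p = 0.088) and Fasn (0.053) were not called.

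Of 7 macrophage and leukocyte markers, 2 rose and 2 fell (2 and 2 adjusted over the list alone): Cd68 and Cd14 rose (2.32 and 1.81), and Itgam and Laptm5 fell (-1.10 and -0.98), and 1 member fell without BAPN replicate 1 or BAPN replicate 2. The median was -0.98, but 0.29 without control replicate 3, the mean -0.06 and the direction of the test upward (camera adjusted p = 0.94). Of 9 Schwann cell and tenocyte markers, 2 rose and 1 fell (2 and 1 adjusted over the list alone): Ngfr and Mkx rose (1.47 and 1.00), and Scx fell (-0.66), Mkx with an edgeR adjusted p of 0.0091, and 0.057 with replicates 1 and 2 summed, with a camera adjusted p of 0.70 for the list. The number that fell was 2 without control replicate 2, with the replicate block and in DESeq2. Of 9 endothelial markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone) by edgeR, or 1 and 1 with the replicate block, with a camera adjusted p of 0.55. Vwf, Eng and Cdh5 had log2 fold changes of 0.36, -0.39 and 0.84 (edgeR adjusted p = 0.053, 0.069 and 0.074, and 0.037, 0.012 and 0.068 with the replicate block). Vwf was called with TMM scaling (edgeR adjusted p = 0.036) and without control replicate 3 (0.029), Eng without BAPN replicate 1 (0.050) or control replicate 3 (0.047), and Cdh5 without BAPN replicate 3 (0.035). At an unadjusted p under 0.05, 2 of these markers were higher and 1 lower in edgeR, and 0 passed the adjusted threshold in DESeq2.

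Cytosolic ribosomal protein genes were slightly lower. Of 45, 0 rose and 27 fell (0 and 34 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 4.8e-05; adjusted p = 0.49 with an estimated correlation). The number that fell was 16, 10, 10 and 13 without BAPN replicate 1, BAPN replicate 2, control replicate 1 and control replicate 2. Rpl3, Rpl14 and Rpl6 had log2 fold changes of -0.38, -0.36 and -0.32. With replicates 1 and 2 summed, 0 ribosomal protein genes fell by edgeR (12 at an unadjusted p under 0.05), while the list kept its call (camera adjusted p = 0.00096). Those 3 genes then had values above the threshold (edgeR adjusted p = 0.057, 0.057 and 0.076). Of 10 mitochondrially encoded transcripts, 0 rose and 1 fell (0 and 1 adjusted over the list alone), with a camera adjusted p of 0.30. The transcript that fell was the ribosomal RNA mt-Rnr2 (-0.95, edgeR adjusted p = 2.7e-04), while mt-Rnr1, the other mitochondrial ribosomal RNA, had 0.17 (edgeR adjusted p = 0.17, and 0.039 with the replicate block) and mt-Cytb -0.19 (0.25). Together, the mitochondrial ribosomal RNAs held 0.572 ± 0.0146% of counts with BAPN and 0.874 ± 0.0283% in controls (SD, n = 3 each). The 10 most abundant genes held 6.26 ± 0.0789% and 8.29 ± 0.772%.

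The genes with the largest increase among those fixed by rule were Adm2 (4.88), Car9 (4.76), Slc7a11 (4.04), Trib3 (4.03), Atp7b (3.69), Cxcl10 (3.66), Adm (3.40) and Prkcb (3.17). Car9, a carbonic anhydrase induced by hypoxia (chromosome 4, 43506966 to 43513729), had a normalized count of 599 ± 98.3 with BAPN and 21.9 ± 11.8 in controls (edgeR adjusted p = 8.4e-05). Adm, adrenomedullin, had 596 ± 49.3 with BAPN and 56.0 ± 12.3 in controls (edgeR adjusted p = 3.0e-05), and Atp7b, a copper-transporting ATPase, 159.5 ± 23.7 with BAPN and 12.3 ± 3.70 in controls (edgeR adjusted p = 9.7e-05). Slc7a11, the cystine transporter, varied widely between BAPN libraries, at 863 ± 579.7 with BAPN and 52.5 ± 8.56 in controls, as did the chemokine Cxcl10, at 135 ± 77.6 with BAPN and 10.7 ± 7.47 in controls (edgeR adjusted p = 0.0011 and 0.0026). The genes with the largest decrease were Heyl (-4.48), Islr (-3.18), Mfap4 (-2.83), C1qtnf3 (-2.74), Adgrg1 (-2.53), R3hdml (-2.43), Ankrd2 (-2.42) and Lrtm1 (-2.36). Heyl (chromosome 4, 123233556 to 123249875) had a normalized count of 36.7 ± 8.10 with BAPN and 825 ± 342 in controls (edgeR adjusted p = 1.9e-04), C1qtnf3 773 ± 91.2 with BAPN and 5169 ± 641 in controls (edgeR adjusted p = 2.4e-05) and Adgrg1, an adhesion receptor of differentiating myoblasts, 532 ± 22.7 with BAPN and 3071 ± 603 in controls (edgeR adjusted p = 6.4e-05).

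In all, 9 of the 31 lists were higher and 9 lower by camera with a preset correlation of 0.01, and 0 and 0 with an estimated correlation, where the smallest adjusted p was 0.11 and 2 were higher and 2 lower at an unadjusted p under 0.05. With the few degrees of freedom of the estimated form, 0 calls do not show that the lists did not shift. In lists with 0 members called one way, other than the G2 and M phase and endothelial lists, at most 1 passed that way at an unadjusted edgeR p under 0.05, and 0 passed in DESeq2. The authors' deposited table gives 2180 genes higher and 2916 lower at an adjusted p under 0.05. Of the genes tested here, 4464 were called by both, 526 here alone and 567 in the authors' deposited table alone, with 0 in opposite directions.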

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

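The test in this part was chosen after the result was seen. The authors' deposited table gives a mean above 0 for 83 of the 503 genes that have no count in any of the 6 libraries, up to 2.70, so a signal is present in values outside the comparison of BAPN with control. For 3324 tested genes that mean lies above the highest of the 6 libraries and for 1695 below the lowest.

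A candidate explanation is that libraries of proliferating cells, not analysed here, entered the authors' fit. Over 58 cell cycle genes, after 2 already noticed were left out, the median log2 ratio of the deposited mean to the mean of the 6 libraries was 1.21. That lies above 100% of 10000 random lists matched on expression, whose highest median was 0.23, while the median for sarcomere genes was -0.54 and for all tested genes -0.02. The test reads cell cycle genes only and does not identify those libraries. If they entered that fit, they could also have entered the authors' size factors used here, under which 2140 genes were higher and 2850 lower, against 2450 and 2381 with TMM scaling of the 6 libraries.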

How the results depend on the processing

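Alternatives chosen after the data were seen were the 2 settings for replicates 1 to 3 (replicate 3 left out, replicates 1 and 2 summed) and the replicate block combined with an estimated correlation or a 2-fold minimum. The cause of each change below was not tested, except where fewer libraries or a stricter threshold make calls harder by construction.

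Against 2140 genes higher and 2850 lower, TMM scaling gave 2450 and 2381, DESeq2 2292 and 2359, and the comparison deposited by the authors gave 2180 and 2916. The median log2 change of all genes was between -0.03 and 0.01 under these scalings. Leaving out 1 library gave 1461 to 2329 higher and 1862 to 3113 lower, with the fewest lower genes, 1862, without BAPN replicate 2. Both libraries of replicate 3 left out gave 3223 and 4265, which rest on the close replicates 1 and 2 alone. Replicates 1 and 2 summed gave 716 and 809, with 2 libraries a group. With these summed, 23 sarcomere and 5 excitation-contraction coupling genes fell, and 21 glycolysis and 12 cholesterol synthesis genes rose. A 2-fold minimum left 545 and 405, and an adjusted p under 0.01 left 1122 and 1515. Genes called here and called again under any of these settings kept their direction, with 0 in the opposite direction.

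The replicate block gave 2790 higher and 3709 lower genes, and with a 2-fold minimum 573 and 427. It called 10 lists higher and 10 lower, adding the S phase and fusion lists. Neither of these 2 passed with replicates 1 and 2 summed (camera adjusted p = 0.16 and 0.097). Among named genes the block added Anln, Ccnb2, Cdc20, Eng, Vwf and mt-Rnr1, and it changed no other call of a named gene or list. With the block and an estimated correlation, 0 lists were higher and 0 lower (1 and 1 at an unadjusted p under 0.05), as were 0 and 0 with an estimated correlation and no block. Apart from estimated correlations, between 8 and 10 lists were higher and between 7 and 10 lower under every alternative run for lists, fry included (8 and 9), which leaves out DESeq2, the authors' table, the 2-fold minimum and the adjusted p under 0.01. Under fry, excitation-contraction coupling and the unfolded protein response had an adjusted p of 0.066 and 0.066, while the fusion list gained a call (0.015, lower). Leaving out 1 library gave 8 to 10 lists each way.

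Among the 117 named genes, 1635 results of other settings with no single library left out comprised 1573 on the same side of the threshold and of 0, 17 that lost a call, 36 that gained one and 9 that changed sign. Of 702 results with 1 library left out, these were 680, 11, 7 and 4. The 17 lost calls arose with replicates 1 and 2 summed, except those of Loxl4 in DESeq2 with the block and in the authors' comparison. The 36 gains fell on Anln, Ccnb2, Cdc20, Cdh5, Eng, Fn1, mt-Rnr1, Pax7 and Vwf. No gene called in the full comparison changed sign. Myf5, at 0.04, changed sign in limma-trend (-0.042, -0.042 and -0.039 with pseudocounts of 1, 0.5 and 10), with the replicate block (-0.026; DESeq2 with the block, -0.0061), with quality weights (-0.33), in the authors' deposited table (-0.014), without replicate 3 (-0.40) and without BAPN replicate 3 (-0.38, the lowest of -0.38 to 0.22). Mki67, at 0.05, was -0.07, -0.06 and -0.16 without BAPN replicate 1, BAPN replicate 2 and control replicate 3, in a range of -0.16 to 0.26. For mt-Cytb the value without replicate 3 was 0.0025.

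At this depth, changes of 1.5-fold were recovered for 53.7% of simulated genes, so a gene that was not called may still differ by that much. Pseudocounts do not enter the edgeR fit and were varied in limma-trend.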

Other observations

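Tests of other cell types, cell cycle, scaling, depth and differentiation in this part were chosen after the results were seen. Those of GC content and of the 4 lists below were written before their results, but those lists were drawn up after the largest changes had been seen, and each was tested on its other members, of which Hes1 and Notch1 had already been counted among the satellite cell markers.

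Imprinted genes, of which Igf2 and Cdkn1c are also in the myogenic list, were often lower with BAPN. H19, a growth-limiting non-coding RNA of muscle, had a normalized count of 205899 ± 11953 with BAPN and 287026 ± 27019 in controls (SD, n = 3 each). For Igf2 it was 52021 ± 6106 with BAPN and 86852 ± 15552 in controls, and for Mest 4560.5 ± 1215 with BAPN and 15885 ± 798 in controls. Of 18 further imprinted genes, 2 rose and 7 fell, among them Meg3 (-1.31), Rian (-1.18) and Mirg (322 ± 75.9 with BAPN and 643 ± 173 in controls), which lie in 1 locus. Their mean log2 change was -0.35 (SE 0.12 over genes), with a camera adjusted p of 0.37, or 0.0050 with the replicate block and 0.97 with an estimated correlation. Whether imprinted genes fall jointly therefore stays open, since the call rests on the block.

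For the other 3 lists no joint shift was detected. After Heyl, Hey1, Notch3 and Lfng, 12 further Notch genes, Hes1 and Notch1 among them, had a mean of -0.16 (SE 0.17, camera adjusted p = 0.95), with Hes1, Hes6 and Dtx4 lower (-0.90, -0.54 and -0.54) and Notch2 and Rbpj higher (0.39 and 0.30). The Notch list mixes receptors, ligands and targets, and members already seen to fall were left out. The result therefore does not decide whether Notch signalling was lower. After Ciart and Bhlhe40, 12 clock genes had a mean of 0.24 (SE 0.16, camera adjusted p = 0.55), with 4 higher and 2 lower, such as Cry1 and Per2 (0.54 and -0.56). After Atp7b, Mt1 and Mt2, 10 copper handling genes had a mean of -0.027 (SE 0.074, camera adjusted p = 0.97), where 2 fell and 1, the importer Slc31a1, rose (0.32).

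The lower level of muscle genes was set against 3 explanations. If all other cell types gained share alike, their markers would all rise. With genes shared with other lists left out, smooth muscle markers had a mean of -0.76 (SE 0.19, 6 of 11 genes). Fibroblast markers had -0.42 (SE 0.20, 10 of 15 genes, the most abundant Lsp1 with a mean of 3480.5), although repeated plating had reduced fibroblasts. Adipocyte markers had 0.43 (SE 0.17, 10 genes), the most abundant Scd1 with a mean of 10149. Skeletal muscle also expresses some smooth muscle markers, such as Synpo2 with a mean of 8352, and the fibroblast mean lies only just over 2 SE below 0. A gain of only some other cell types would leave markers of the rest unchanged or lower. A lower share of muscle cells, or a change within the other cell types, is therefore not excluded. After a trend on GC content and exon length was removed in the fit with the replicate block, the sarcomere median was -0.84, from -0.88 before. Whether more cells were left proliferating stays undecided, since the G2 and M phase list had a mean over pairs of -0.025 with an SD of 0.11, while S phase genes had pair medians of 0.23, 0.18 and 0.25. A slower differentiation under BAPN, which the design names, stays open.

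The higher level of glycolysis and hypoxia genes had a median of 1.26, and of at least 1.30 under TMM, upper quartile and median-ratio scaling, and 1.40 after the trend on GC content and length was removed, from 1.27 before with the block. The second test argues against base composition or length as the whole cause. The scalings tried differ little, with a median over all genes of -0.032 in the main fit and 0.013 under TMM. They could not have brought the list near 0, so they do not decide on scaling as a cause. An effect of BAPN, which the design names, remains open.

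Replicate 3 stood apart in both groups. Lower depth is argued against, since with all libraries thinned to 17125602 counts the chi-square per gene between replicates 1 and 3 was at least 8.57 times that between 1 and 2. A candidate explanation is that these cultures were further along differentiation. Sarcomere genes were higher in replicate 3 than in the mean of replicates 1 and 2, with medians of 0.50 with BAPN and 0.56 in controls, and G2 and M phase genes lower, with medians of -0.50 and -0.69. Several lists moved unequally in the groups there, and these differences were not tested. The unfolded protein list was 0.73 higher in replicate 3 with BAPN and 0.20 in controls, and the cholesterol list -0.36 and 0.48. Opposite signs were also seen, among others, for macrophage (-0.26 with BAPN and 0.75 in controls), mitochondrial (-0.27 and 0.28), adipocyte (-0.34 and 0.16), endothelial (-0.29 and 0.21) and smooth muscle lists (-0.13 and 0.30).

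The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4990 genes by edgeR, as many as in 1 split, itself, and the highest of the other 9 was 0, with at most 727 genes at an unadjusted p under 0.05. Each of the other 9 mixes BAPN and control libraries, so the difference between them adds to the spread within groups and makes calls harder. The contrast of 4990 with 0 therefore does not tell whether the grouping arose by chance. Of those 9 splits, 3 also part all 3 pairs, and they gave 0 genes each, with 38 to 188 unadjusted. DESeq2 was not run on the other splits.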
